A study of Zea mays with 8 samples.

How the data were processed

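Total RNA of the stem internode below the ear was hybridised to Affymetrix maize arrays by the authors. The deposited values are log2 expression per probe set after RMA, run in Affymetrix Expression Console per the submitters' processing notes, which give no versions. RMA corrects background, makes the probe distributions of the arrays equal and summarises the probes of a set, so a shift of all transcripts together would not be seen in them. Per the labels, RNA was extracted from 4 plants of each line and treatment, and 250 ng were labelled. Whether the 4 plants were pooled for each array is not given in the sources used here.

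The 8 arrays were grouped by the titles into 4 control and 4 infested arrays, and the replicate numbers 1 to 4 stand for the lines CM151, EP39, EP42 and PB130. For the infested CM151 array, 1 label gives the line as CM152 and another as CM151. The array was used as CM151. Deviations from the group means of the infested and the control array with the same number correlated across probe sets at 0.864, 0.868, 0.822 and 0.793 in the 4 lines, and the highest correlation of an infested array with a control array of another line was -0.153. The number therefore pairs the arrays by line. With 1 array per line and group, p-values measure the spread of the infestation difference between lines, not between plants of a line.

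The 113 Affymetrix control probe sets were left out, which leaves 17621 of 17734. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the line as a block, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The standard errors are those of the moderated fit, with 6.02 degrees of freedom. Line differences used the limma F test over the 3 line coefficients with infestation in the model. The response within a line has no replicate and was not tested.

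Gene names came from the platform annotation, through which 1108 genes are named, and 1060 of these matched by gene number a table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. The other 48 keep the name of the annotation. No coordinates are given, since the build behind the array is not given in the sources used here.

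Gene lists were written as name patterns before the data were examined. The annotation holds names and no descriptions, so membership was then corrected on the names alone, before any test: namesakes were removed and members with other spellings added. All 7 genes of the pollen and anther list entered this way. Of 24 lists, 18 had 5 or more measured genes and were tested with camera at a preset correlation of 0.01, against all 1108 named genes, with the probe set of highest mean for each gene. Camera with an estimated correlation and fry were run beside it. Counts are given over all probe sets and adjusted over the list alone.

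The genes named in the text follow a rule fixed before the data were examined. For infestation these are up to 12 genes in each direction among those past the threshold with the same sign in all 4 lines, filled up to 6 with the genes of smallest p, given as values. For each list they are up to 4 members of smallest p, for the lines the 8 genes of largest F, and for the response the 3 largest differences in each line. After their values were seen, opr5, aoc1, hpl1, opr8, opr7, opr3 and cc7 were also named, to complete their lists' counts. Also named after their values were seen are gst31, gst37, GST38 and GST26, which passed over their list alone, and hsp18a for its opposite directions. The gene incw1 was named in the same way, since it moved against its list mean.

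The alternatives were a fit without the block, a filter on mean level, quantile normalization, median centring, an intensity trend with robust settings, array weights, a minimum difference of 1, a threshold of 0.10, all probe sets of listed genes, and each line left out in turn. Lists by pattern alone, all probe sets as list background and adjustment over the named probe sets alone were added after seeing the data.

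The fits were tested on simulated data with the real line means. Of 50 changed probe sets per size among 17621, the infestation fit called 6% at a log2 size of 0.5, 80% at 1, 98% at 2 and 100% at 4, with 7 false calls among 149. The line test called 90% of 200 probe sets shifted by 2, with 7 false calls among 187. For the lists, among 1108 genes, both shifted lists were called, with 1 false call. Each simulated infestation shift was equal in all 4 lines, and the noise was independent between probe sets. In the data tps6, at 5.11 with an SD of 2.15 over the lines, missed the threshold (limma adjusted p = 0.108). The simulated shares therefore do not give the power for responses that vary between lines, nor for lists of correlated genes.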

Results

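RNA from maize stems was measured on 8 arrays, 1 control and 1 infested array for each of 4 unrelated inbred lines, CM151, EP39, EP42 and PB130. The infested plants carried a mass of about 40 eggs of the pink stem borer *Sesamia nonagrioides*, a moth whose larvae tunnel in the stalk, on the sheath of the main ear at tasseling. The internode below the ear was collected 15 days later from infested and control plants. The array medians lay between 6.58 and 6.64 on the log2 scale, and the number of arrays, not a read depth, limits the precision of each value. Of 17621 probe sets tested, 1452 are paired with 1 gene in the annotation used, 1 with several genes and 16168 with none, so most probe sets that changed have no gene name here.

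The first comparison asked which transcripts differed between infested and control stems. Transcripts rose in the infested stems, and among the named ones were LOC100037814, LOC100037813, the lipoxygenase gene lox3 and gpc4 (LOC100037774), a cytosolic glyceraldehyde-3-phosphate dehydrogenase gene of glycolysis. LOC100037814 rose by 5.03 ± 0.22 on the log2 scale (SE, n = 4 lines; limma adjusted p = 0.00526) and LOC100037813 by 4.30 ± 0.22 (adjusted p = 0.00599). For lox3 the rise was 2.37 ± 0.20 (adjusted p = 0.0318), to a mean of 9.37 in infested arrays. The gpc4 transcript rose by 1.71 ± 0.14 (adjusted p = 0.0318). Each of these 4 genes was higher in the infested array of all 4 lines.

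In all, limma with the line as a block called 26 probe sets, 26 higher and 0 lower, and all 26 had the same sign in the 4 lines. Their log2 differences ran from 0.95 to 5.63, and 25 of them reached 1 or more. The 2 largest, at 5.63 and 5.38, belong to probe sets without a gene name here, and 22 of the 26 are unnamed. At an unadjusted p under 0.05 limma gave 948 higher and 1317 lower probe sets, so the count of 0 lower calls comes after adjustment. These unadjusted counts were 833 and 830 without EP42, and 851 and 816 without PB130. With the block left out, the fit called 0 probe sets, since the difference between lines then enters the error. At an unadjusted p under 0.05 that fit gave 389 probe sets, 264 higher and 125 lower. Leaving out CM151, EP39, EP42 or PB130 gave 17, 3, 6 and 15 calls, of which 7, 3, 6 and 13 were among the 26. Without CM151, 1 of the 17 was lower. An intensity trend with robust settings gave 40, of which 21 were among the 26. Of the named calls, LOC100037814 passed without any of the 4 lines, LOC100037813 had an adjusted p of 0.0578 without EP39, lox3 passed only without PB130, and gpc4 in none of these fits.

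Other named genes had the same sign in all 4 lines and missed the threshold. The wound-induced proteinase inhibitor gene wip1 (LOC542729) stood 3.64 ± 0.42 higher (adjusted p = 0.0623) and the safener-induced gene In2-1 (LOC542388) 1.77 ± 0.21 higher (adjusted p = 0.0647). On the lower side the potassium channel gene kch3 (LOC542145) differed by -0.96 ± 0.14 (adjusted p = 0.0974). The sizes for In2-1 and kch3 are inexact, since their control levels lay below the 25th percentile of the array in CM151 and PB130 for In2-1 and in EP39 and PB130 for kch3. The ADP-glucose pyrophosphorylase gene bt2 (LOC541902) differed by -0.68 ± 0.12 (adjusted p = 0.150), and pdrp1 (LOC732785), whose product regulates pyruvate orthophosphate dikinase, by -0.73 ± 0.15 (adjusted p = 0.183). For LOC732726, lem1 (LOC732840) and rnc1 (LOC100125654), differences of -0.39, -0.45 and -0.47 had adjusted p of 0.183, 0.186 and 0.192.

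**Figure D1:**
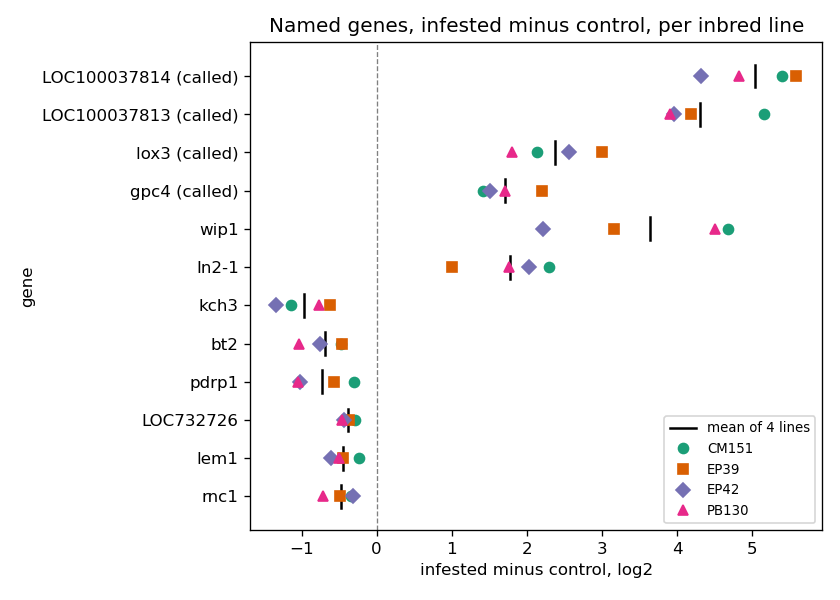
Infested minus control on the log2 scale (x axis) for the 12 named genes of the infestation comparison (y axis); points are the 4 inbred lines, black bars their mean, and the genes called by limma are marked. LOC100037814 lies between 4.32 and 5.58 in the 4 lines, and the 6 lowest genes lie below 0 in every line.

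The second question was whether genes of one pathway moved together against the other named genes. Genes of jasmonate and oxylipin synthesis, which make oxygenated fatty acid products, jasmonate among them, rose as a list, with a mean of 0.90 (SD 0.99 over 10 genes; camera adjusted p = 8.15e-05). With an estimated correlation the adjusted p was 0.225. The opr1 transcript was 2.52 ± 0.37 higher, lox3 2.37 ± 0.20, aos1, which encodes allene oxide synthase, 1.63 ± 0.34, and lox1 1.36 ± 0.25. The size for opr1 is inexact, with a control level under the 25th percentile in CM151 and PB130. With opr5, these made 5 of 10 genes higher when adjusted over the list alone, against 1 of 10 over all probe sets. Without the block opr5 did not pass. The rest of the list did not pass, so the rise was not shown for all members. There aoc1 stood at 0.26, hpl1 (LOC542163) at 0.16, opr8 at 0.062, opr7 at 0.041 and opr3 at -0.025. The list mean was between 0.67 and 1.19 in every line.

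Proteinase inhibitors, proteins that block digestive enzymes of herbivores, rose as a list by a mean of 1.44 (SD 1.51 over 5 genes; camera adjusted p = 0.00966), with an adjusted p = 0.429 with an estimated correlation. Adjusted over the list alone, 3 of 5 were higher, and 0 over all probe sets. They were wip1 at 3.64 ± 0.42, the cystatin gene cpi2 (LOC100101525) at 2.05 ± 0.31 and psei1 (LOC542213) at 1.40 ± 0.33, which did not pass without the block. The cystatin genes cc3 (LOC732752) and cc7 (LOC732754) stood at -0.16 and 0.27 and did not pass.

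Pathogenesis-related genes rose as a list by a mean of 1.36 (SD 1.08 over 6 genes; camera adjusted p = 0.0137), and the adjusted p = 0.354 with an estimated correlation. Adjusted over the list alone, pr5 (LOC542720) was 2.15 ± 0.41 higher, the chitinase gene chn1 (LOC542525) 1.79 ± 0.37 higher and the zeamatin-like gene zlp (LOC542299) 1.63 ± 0.25 higher, while prp2 (LOC542195) fell by 0.58 ± 0.13. That is 3 higher and 1 lower of 6, against 0 over all probe sets, and none of these 4 genes passed without the block. Without EP39 the list had an adjusted p = 0.0803.

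Glutathione transferases and scavengers of reactive oxygen, which detoxify foreign and oxidised compounds, rose as a list by a mean of 0.45 (SD 0.83 over 37 genes; camera adjusted p = 3.64e-05). The adjusted p = 0.225 with an estimated correlation. Adjusted over the list alone, 12 genes were higher and 2 lower, and 0 over all probe sets. GST25 (LOC541838) was 3.76 ± 0.58 higher, gst31 (LOC541842) 2.54 ± 0.48, gst2 (LOC542311) 1.80 ± 0.30, the superoxide dismutase gene Sod4A 0.75 ± 0.13 and gst1 (LOC542366) 0.47 ± 0.08. On the lower side were GST38 (LOC541847) at -0.49 ± 0.12 and GST26 (LOC541839), near the floor in the EP39 control, at -0.31 ± 0.09, and neither passed without CM151, EP39 or EP42. Of the genes called over this list, gst2, GST25 and Sod4A passed with each line left out in turn, whereas gst31 and gst1 did not pass without CM151. Without the block, none of the called genes of this list passed. The list mean was between 0.35 and 0.53 in each line.

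Photosynthesis genes fell as a list by 0.30 on average (SD 0.16 over 15 genes; camera adjusted p = 0.000495), and all 15 were negative. The adjusted p = 0.617 with an estimated correlation, which was 0.787 between its genes. Over the list alone 0 of 15 passed. The photosystem gene psbs1 (LOC542126) stood at -0.68 ± 0.19, the ferredoxin reductase gene L-FNRI (LOC542558) at -0.55 ± 0.16 and rca1 (LOC541712), the Rubisco activase gene, at -0.51 ± 0.13. By line the list mean was -0.0040 in CM151, -0.12 in EP39, -0.42 in EP42 and -0.65 in PB130, and without PB130 it was -0.18 (adjusted p = 0.0266).

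The other 13 lists tested did not pass camera with all 4 lines. Without PB130, camera called benzoxazinoid (mean 0.80, adjusted p = 0.0463), peroxidases (0.45, adjusted p = 0.0463), heat shock (0.59, adjusted p = 0.0359), cysteine proteinases and senescence (0.23, adjusted p = 0.0325) and sugar and starch (-0.10, at the edge of the threshold). For all of these but sugar and starch, leaving out EP39 or EP42 gave smaller means that were not called. Without EP42 they were 0.58 for benzoxazinoid, 0.12 for peroxidases and 0.038 for cysteine proteinases and senescence. Without EP39 heat shock had 0.18. Without CM151 the benzoxazinoid mean was larger, at 1.25, and called. Sugar and starch was not called without CM151, EP39 or EP42, at -0.124, -0.119 and -0.111. In the terpenoid list (mean 0.81, adjusted p = 0.384) the sesquiterpene synthase gene tps6 (LOC542688) was 5.11 ± 0.76 higher and passed over the list alone (adjusted p = 0.00589, and 0.0808 without the block), 1 of 11 genes. The copalyl diphosphate synthase gene an1 stood at -0.74 ± 0.23 and TPS4 (LOC542754) at 0.64 ± 0.19, both short of it. Control levels under the 25th percentile, in all 4 lines for TPS4 and in CM151 and PB130 for tps6, make these sizes inexact. In the phenylpropanoid and lignin list (mean 0.14, median -0.11, direction of the camera test down, adjusted p = 0.610) the cinnamoyl-CoA reductase gene ccr2 (LOC542735) was 2.06 ± 0.49 higher and the laccase gene LAC1 (LOC606456) 0.67 ± 0.14 lower, both over the list alone. Neither call held throughout: ccr2 did not pass without EP42, nor LAC1 without EP39 or without the block. In sugar and starch (mean -0.11 over 32 genes, adjusted p = 0.109) bt2 was the 1 gene lower over the list alone (adjusted p = 0.0411), and it did not pass without CM151, EP42 or PB130, or without the block. The starch genes GLG1, zSSIIb (LOC541656) and zpu1 (LOC541711) stood at -0.36 ± 0.08, -0.32 ± 0.08 and -0.36 ± 0.09, negative in all 4 lines and short of the list-alone threshold (adjusted p = 0.0597 each). At the same adjusted p, incw1 (LOC542314) of this list stood at 1.29 ± 0.35, positive in all 4 lines. In all, 10 genes of the list were positive and 22 negative. Benzoxazinoid genes, which make the hydroxamic acids of maize defence, had a mean of 0.85 (adjusted p = 0.160, and 0.0489 without CM151), and the glucosidase gene glu1 (LOC542414) stood at 2.76 ± 0.99.

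Cell wall carbohydrate genes had a mean of 0.08 (adjusted p = 0.131, and 0.0279 against all probe sets, an alternative added after seeing the data), with the expansin gene expB7 (LOC542649) at -2.74 ± 0.68 and 0 of 32 genes past the list-alone threshold. Heat shock genes had a mean of 0.39 (adjusted p = 0.289), with hsp22 (LOC542602) at 2.13 ± 0.64 and hsp101 (LOC541780) at 1.28 ± 0.45. The means were 0.30 for peroxidases (adjusted p = 0.160), 0.14 for cysteine proteinases and senescence (adjusted p = 0.160), 0.12 for cell division (adjusted p = 0.693), -0.08 for water deficit and abscisic acid (adjusted p = 0.788) and -0.00099 for cytosolic ribosomal proteins (median 0.0045, direction of the camera test up, adjusted p = 0.801). Markers of other tissues had means of -0.06 for kernel storage (adjusted p = 0.610) and 0.15 for pollen and anther (adjusted p = 0.314). Without EP42 camera called the pollen and anther list, with a mean of 0.33 (adjusted p = 0.0487). The pollen and anther mean was 0.81 in CM151, 0.45 in EP39, -0.41 in EP42 and -0.25 in PB130.

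Lists with fewer than 5 measured genes were not tested as lists in the main fit. With all probe sets of the listed genes, lipid transfer had 5, and 4 of them belong to the gene PLTP. Camera at the preset correlation called the list higher (mean 0.43, adjusted p = 0.00192), but probe sets of 1 gene are not independent members. Adjusted over the list alone, the anthocyanidin synthase gene a2 (LOC606406) of the flavonoid list was 0.63 ± 0.14 higher and the lipid transfer gene PLTP 0.76 ± 0.24 higher, each 1 of 2 genes. Neither passed without the block, and PLTP did not pass without CM151, EP42 or PB130, with a trend and robust settings or with array weights. The means were 0.55 for shikimate and tryptophan (2 genes), 0.28 for flavonoid, 0.56 for lipid transfer and 0.13 for ethylene (3 genes), and no gene of the WRKY or auxin lists was among the named genes. By fry, which asks whether a list moves one way, jasmonate and oxylipin and sugar and starch passed, both with an adjusted p of 0.0221. The other lists called by camera did not pass fry. Their fry adjusted p was 0.110 for proteinase inhibitors, 0.0759 for pathogenesis-related, 0.0712 for glutathione transferases and scavenging and 0.309 for photosynthesis. Camera with an estimated correlation called 0 of 18 lists. The estimate was -0.017 for jasmonate and oxylipin, -0.0080 for pathogenesis-related, 0.022 for glutathione transferases and scavenging and 0.383 for proteinase inhibitors. For the first 2 of these it lay below the preset 0.01, so a higher correlation between genes is not what ended those calls. With the preset correlation camera called 4 lists without EP39 and 10 without PB130, 8 of them up.

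**Figure D2:**
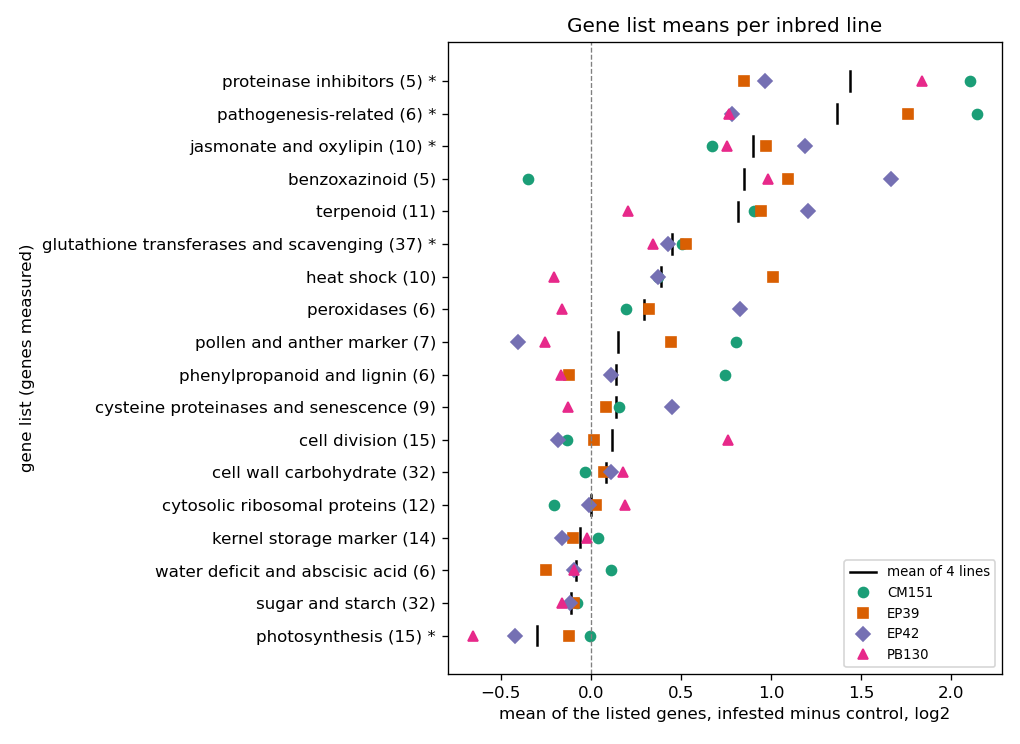
Mean infested minus control difference on the log2 scale (x axis) for each of the 18 lists tested, with the number of genes measured (y axis); points are the 4 inbred lines, black bars the mean over lines, and a star marks a list called by camera. The glutathione transferase list lies between 0.35 and 0.53 in the 4 lines, whereas the benzoxazinoid list runs from -0.35 in CM151 to 1.66 in EP42.

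The lines also differed from each other. The GTPase gene rop6 (LOC542017) averaged 8.66 in EP42 and between 3.15 and 4.12 in the other lines (SD 0.19 in EP42, n = 2 arrays; limma F test, adjusted p = 1.67e-05). The gene ser1 (LOC541989) averaged 3.78 in CM151 and 7.57 to 8.04 elsewhere (adjusted p = 2.44e-05). On 1 of the 4 probe sets of PLTP, levels were 8.37 and 8.58 in CM151 and EP39 against 5.48 and 5.13 in EP42 and PB130 (adjusted p = 3.99e-05). On the probe set used for its list, PLTP was lowest in CM151 and EP39, at 9.03 and 9.38, and highest in EP42, at 10.6 (adjusted p = 0.0406), so the probe sets disagree. The response regulator gene RR4 (LOC541630) was also higher in CM151 and EP39, at 7.25 and 6.05, than in EP42 and PB130, at 4.21 and 4.33 (adjusted p = 5.15e-05), and its other probe set had the same order of these pairs, with line means 1.47 apart. LOC100125656 was highest in EP42, at 7.98 (adjusted p = 6.99e-05).

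For pal3 (LOC542258), a phenylalanine ammonia-lyase gene at the entry to phenylpropanoid synthesis, the level was 7.67 in EP42 and 11.9 to 12.6 in the other lines (adjusted p = 0.000107). The phosphoenolpyruvate carboxylase gene pep1 (LOC542372) ranged from 6.27 in EP39 to 10.4 in CM151 (adjusted p = 0.000115), and hcf106 (LOC732790), a thylakoid protein transport gene, from 5.06 in EP39 to 8.26 in CM151 (adjusted p = 0.000118). In total 7315 probe sets, 41.5% of those tested, differed among lines, and 4319 of them had line means at least 1 apart. Without EP39 the count was 4571 and without CM151 4711. Without CM151 the ser1 call ended (adjusted p = 0.0739), and without EP42 the pal3 call (adjusted p = 0.0559). Probe mismatch in a line, which could hide a transcript there, was not tested for the line differences, so they are differences in signal. The rop6 control levels lay below the 25th percentile of the array in CM151 and EP39.

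The last comparison sets the response of each line beside the others, as values without a test, since each line has 1 control and 1 infested array. LOC100037814 was among the 3 largest named differences in CM151, EP39 and PB130, at 5.40, 5.58 and 4.82. In CM151 the largest were those of tps6, at 8.22, and the pathogenesis-related gene prp4 (LOC542352), at 5.64, which stood at 3.36 in EP39, 0.25 in EP42 and 0.15 in PB130. The prp4 control level was 4.46 in CM151 and 4.89 in EP39, against 10.3 in EP42 and 9.97 in PB130. GST25 led in EP39, at 6.01. The terpene synthase gene TPS9 (LOC542689) stood at 8.59 in EP42 and 5.43 in EP39, against 0.07 in CM151 and 0.14 in PB130. Its control levels, 2.50 to 3.32, lay below the 25th percentile of the array in every line, as did those of tps6 in CM151 and PB130, piip1 in EP42 and pdc1 in PB130, so the sizes of these differences are inexact. EF1-A (LOC542581), at 5.77, and piip1 (LOC542597), at 5.16, followed in EP42. In PB130 tps6 stood at 4.77 and the pyruvate decarboxylase gene pdc1 (LOC542376) at 4.75, against 1.27 or less in the other lines.

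Differences of at least 1 numbered 199 higher and 33 lower probe sets in CM151, 305 and 70 in EP39, 436 and 143 in EP42, and 586 and 348 in PB130. Of these, 54 were higher in all 4 lines, 12 of them named, and 0 lower in all 4. At any size, 1388 probe sets were higher and 2540 lower in all 4 lines. That is 22.3% of probe sets with the same sign throughout, where random signs would give 12.5%. The median difference over all probe sets was -0.030, and it was below 0 in each line, so a small common offset enters the count of lower ones. Across probe sets, which are not independent replicates, the differences of 2 lines correlated with a Pearson r between 0.363 and 0.517. RNA quality, read as the 3' minus 5' signal of 5 control transcripts, differed by -0.07 between infested and control arrays (SD 0.21 over 4 lines; exact sign-flip p = 0.750, where the smallest possible is 0.125).

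**Figure D3:**
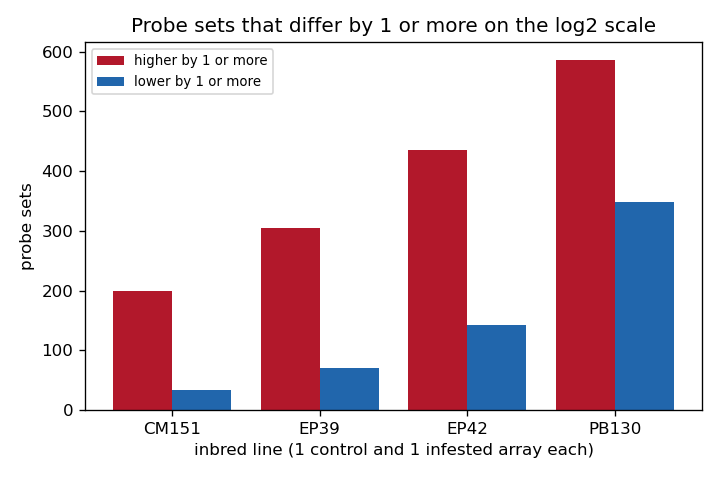
Number of probe sets (y axis) higher or lower in the infested than in the control array by at least 1 on the log2 scale, for each inbred line (x axis, 1 control and 1 infested array each). The bars go from 199 higher and 33 lower in CM151 to 586 higher and 348 lower in PB130.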

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

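The tests of probe mismatch, green tissue share and bright probe sets were chosen after the results were seen, and the counts over other splits before.

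One array lay far from the other 3 of its group for 12 genes and 1 marker list. Dixon's criterion marked 14 of 238 groups of 4, and chance alone marks about 1 in 20, or 11.9. The 4 arrays of a group are 4 different lines, so a mark can be a line difference, which the 1 in 20 does not allow for. Thus orp2 stood at 5.17 and 5.24 in the control and infested arrays of PB130. In the infested group wip1 was 10.3 in CM151 against 12.5 to 12.7, bx1 6.55 in CM151 against 9.46 to 9.75, bm1 12.2 in EP39 against 12.5 to 12.6, and rpl29 10.1 in CM151 against 9.68 to 9.74. In the control group gst37 was 3.89 in EP42 against 5.67 to 5.82, glu2 3.51 in PB130 against 2.16 to 2.37, orp2 5.17 in PB130 against 7.34 to 7.72, PER42 10.7 in EP42 against 9.97 to 10.04, and Zea m 3 3.54 in EP42 against 3.45 to 3.46, the control levels of glu2 and Zea m 3 lying below the 25th percentile of their arrays. Genes picked for their line differences were marked too: rop6 at 8.80 in the EP42 control, ser1 at 3.76 and 3.79 in the CM151 control and infested arrays, and pal3 at 7.35 in the infested EP42 array. The pollen and anther mean was 3.26 in the CM151 control array against 3.54 to 3.57 in the other controls.

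Among the 113 genes checked, lines moved in opposite directions by at least 1 for 2, a difference that was not tested. Over all probe sets 0 to 13 did so in each pair of lines, among them hsp18a (LOC542293) of the heat shock list, at 1.36 in CM151 and -1.69 in PB130. The benzoxazinoid gene bx1 stood at 1.95 in EP42 and -1.15 in CM151, and the peroxidase gene pox2 at 4.66 in EP42 and -1.92 in PB130.

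Affymetrix control probe sets, left out of the comparisons, held a signal as well. The glyceraldehyde-3-phosphate dehydrogenase controls AFFX-Zm-gapdh-M_at and AFFX-Zm-gapdh-M_s_at were 1.62 and 1.41 higher in infested arrays, between 1.36 and 1.92 and between 1.17 and 1.77 in the 4 lines.

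Arrays of a line were also exchanged between the groups, which gives 8 splits that part all 4 pairs, the real one included. The real split called 26 probe sets and the highest of the others 0, so 1 of 8 splits reached the count. For the lists 3 of 8 splits reached the 5 called, and the highest of the others, with the PB130 pair exchanged, called 10. With 8 splits no share can go under 0.05, so these counts are too few for a test.

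The photosynthesis list was lower in infested plants by 0.30 on average. An offset of bright probe sets is argued against: 5557 probe sets of the same brightness had a median difference of -0.047, and 0 of 10000 brightness-matched random lists had a mean as low, the lowest being -0.28. The random lists drew unrelated probe sets, while the photosynthesis genes had an estimated correlation of 0.787. The count therefore bears on brightness alone and is no test of the fall of the list. A smaller share of green tissue in infested pieces may lower all members alike. In PB130, the line of the lowest mean, the members had an SD of 0.26 around -0.65, which does not decide between an even and an uneven fall. It cannot be told apart from a response to infestation, which stays open and untested.

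Named genes that responded in some lines and not in others were counted on the probe set of highest mean for each gene, where infested minus control reached 3 in 1 line and stayed under 0.5 in size in another, which gave 7 genes and 12 gene and line pairs. The count took higher levels alone, so expB7, at -4.63 in PB130 and -0.34 in EP42, is not in it. It also leaves out piip1, at 5.16 in EP42 and 0.35 in CM151 on a probe set that is not its highest. Probe mismatch in the lines without a response could hide a transcript there. For prp4 the levels argue against it. The control level was at percentile 90.5 or higher of the array in EP42 and PB130, 10.3 and 9.97 on the log2 scale. In CM151 and EP39 the prp4 control levels were 4.46 and 4.89, and the infested levels 10.1 and 8.25. Without infestation EP42 and PB130 thus already stood near or above the infested levels of CM151 and EP39. Whether the probe set reads prp4 alone was not tested. Over all pairs 25% had a control level above the array median and 41.7% lay below the 25th percentile on both arrays, among them TPS9, at 2.57 in CM151 and 2.50 in PB130. For genes near the floor, mismatch and a missing response cannot be told apart, and a difference between the lines themselves was not tested.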

How the results depend on the processing

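The count of 26 probe sets was within 1.5 times under the filter, quantile normalization, median centring, array weights and a minimum difference of 1. A like count is not the same set. The filter kept 18 of the 26 and called these 18 among its 26 calls. Of the main 26, quantile normalization called 22, median centring 26 and array weights 25. The count was 0 with no replicate block, 40 with a trend and robust settings (38 higher, 2 lower) and 74 at a threshold of 0.10. It was between 3 and 17 with 1 line left out. Fewer arrays entered the last. In all 10 other fits each of the 26 that was measured stayed positive. Since all 26 were higher in every line, their sign could hardly turn, so this adds no support. Without the block 389 probe sets had an unadjusted p under 0.05, and the smallest adjusted p was 0.0718. All 4 named calls were lost without the block, the list calls were 5, and 7 of the 32 list-alone calls held. With each line left out in turn, 17 of the 32 held throughout.

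The 5 list calls became 3 with the filter, which left 9 lists to test, 0 with camera and an estimated correlation, 4 to 10 with 1 line left out, and 6 of 19 lists with all probe sets of the listed genes, lipid transfer being the one gained. Alternatives added after seeing the data gave 5 calls with lists by pattern alone and 6 with all probe sets as background. Lists near 0 that had not been called changed sign. With 1 line left out, phenylpropanoid and lignin ran from -0.058 to 0.24, cell division from -0.10 to 0.22, ribosomal proteins from -0.064 to 0.068 and pollen and anther from -0.071 to 0.33, which camera called without EP42 (adjusted p = 0.0487). Ribosomal proteins stood at 0.0026 with all probe sets of the listed genes and kernel storage at 0.082 with lists by pattern alone. The cause was not tested.

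The 7315 probe sets that differ among lines became 4319 with line means at least 1 apart, and 4571 to 6308 with 1 line left out. Counts of the response within each line stayed within 1.5 times under both scalings. Adjustment over the 1452 named probe sets alone, also added after seeing the data, gave 9 calls in place of 4, all higher. Probe sets near the array floor cannot show a fall.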

Other observations

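The tests and genes in this part were chosen after the data were seen. Beside gpc4, which was called, the cytosolic glyceraldehyde-3-phosphate dehydrogenase gene gpc3 (LOC542333) was higher on 2 probe sets, by 1.37 ± 0.17 and 1.11 ± 0.14, in all 4 lines. Both passed when adjusted over the named probe sets alone (adjusted p = 0.0334) and missed over all probe sets (adjusted p = 0.0706 and 0.0722). Over the named probe sets alone EF1-A (LOC542581) at 3.96 ± 0.50, wip1 and In2-1 passed too. Whether the EF1-A probe set reads this gene alone was not tested.

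The cell division list was not called (adjusted p = 0.693), and its members in PB130 are given as values without a test. There the helicase subunit genes MCM6 (LOC542206) and MCM7 (LOC542504) stood at 2.54 and 2.01, the sliding clamp gene pcna2 (LOC542357) at 2.03, and the histone genes his1 (LOC542385) and his2b5 (LOC542301) at 1.86 and 1.41. These are 5 of 15 cell division genes with a difference of at least 1 there, against 0 in CM151, EP39 and EP42. Of the other members in PB130, his1a (LOC541964), pcna1 (LOC542425) and cdc2 (LOC542270) stood at 0.87, 0.73 and 0.64, and cenH3 (LOC542500) and mad2 (LOC542621) at -0.14 and -0.77. The mean of the list was 5.56 in the PB130 control array, the lowest of the 4 controls, and 6.32 in the infested one, which lies between the infested means of EP42, at 5.77, and CM151, at 6.49. The glucosidase gene glu1 stood at 5.02 in EP39, 4.92 in EP42 and 1.96 in PB130, and at -0.87 in CM151. The transcript LOB21 (LOC100125645) stood at 4.24 in PB130 and between -0.07 and 0.02 in the other lines, with control levels of 2.54 to 3.04, below the 25th percentile of every control array, so the size is inexact.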
